A study of Mus musculus with 12 samples.

How the data were processed

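RNA from the brains of 12 mice was analysed, 4 WT, 4 Old and 4 New. Per the labels' protocols, RNA was extracted from frozen tissue, libraries were made from polyA-selected RNA with an Illumina TruSeq mRNA v2 kit, which does not mark strand, and paired-end reads were sequenced with 4 barcoded samples to a lane. A label on each sample describes the libraries as depleted of ribosomal RNA, which differs from the protocol. Lane assignments and the sex of the mice are not given in the sources used here. Per the labels' protocols, WT mice were purchased and the knockout mice were housed by the laboratory, so the origin of the animals goes with genotype and every comparison against WT carries both.

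The authors deposited 1 table of FPKM values with 27131 genes and 1 column per sample. Per the submitters' processing notes, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks, Cuffdiff 2.1.1 and FastQC were used with the mm10 build. The gene annotation, the normalization between libraries and the strand setting are not given in the sources used here. Cuffdiff divides reads between transcripts by estimation, so genes with near-identical copies or overlapping partners are uncertain, and an FPKM of exactly 0 means only that a gene is listed at 0. Because FPKM holds no counts, the read depth is unknown, no interval for counting error was computed, and precision rests on the spread between 4 mice per group. Sums of FPKM ran from 385096 to 527104 per library, and the 10 genes with the highest values took 32.0% to 49.8% of the sum. No pair of libraries held identical values. Of the row names, 25 had been turned into dates, 21 of them among the tested genes, and these rows have no gene name here.

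Coordinates come from GENCODE M21 on the same build. Row names matched by symbol (20672), by Ensembl identifier (3914) or by synonym (1839), and 681 other rows were left without coordinates. GC content was taken from the longest annotated transcript and was known for 97.9% of tested genes.

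Samples were grouped by their titles. Genes with a mean FPKM of at least 0.5 over the 12 libraries were tested (16203 genes). Values were analysed as log2(FPKM + 0.1), so a fold change is on that scale and understates changes of low genes. All 3 groups were fitted together with limma 3.58.1 (trended empirical Bayes) in R 4.3.3, with contrasts Old minus WT, New minus WT, Old minus New and the mean of both strains minus WT. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Exact two-sided permutation tests used all 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286. Fisher's exact tests compared genes near Plat with genes elsewhere, leaving out Plat, and were adjusted over 32 tests.

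Before the data were examined, 36 gene lists were fixed for pathways, brain cell types and regions, the fibrinolysis system, stress, sex and RNA quality. The 35 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. The mitochondrially encoded list had 0 genes in the table. Fry's directional test passed 0 lists in every contrast. Its test for change in either direction passed 1 list, that holding Plat, in each of the 3 comparisons with WT and 0 in Old against New.

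Genes were named by a rule also fixed before the data were examined. The rule took Plat, the 12 largest rises and falls among called genes with at least 1 FPKM in the higher group, called genes within 10 Mb of Plat, up to 4 members with the smallest p from each list that passed or held a called gene, and members of the fibrinolysis list. Other genes are said to be chosen after their values were seen. Not every gene the rule took is reported here.

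The procedure was tested on simulated data. For each of the 3 comparisons between groups, 20 simulations of 16203 genes were drawn, with 200 genes changed. Means and spreads came from the 10 libraries other than WT 4 and Old 1. The averaged deviation of WT 4 and Old 1 was added to both alike. It cancels in the difference between Old and WT, whereas the real deviations were not equal. Recovery and false calls for that comparison therefore leave out this inequality. Changes of 2-fold were recovered in 72.5% of genes for Old against WT, 74.35% for New against WT and 71.85% for Old against New, and changes of 4-fold in 94.6%, 94.7% and 95.2%. False calls averaged 1.25, 1.95 and 1.95 genes. A list of 30 genes shifted by 0.5 passed camera in 20 of 20 simulations of each comparison and an unshifted one in 0. Genes were drawn independently and lists at random, and passing meant an unadjusted p under 0.05. In the real lists members were correlated, with estimates of 0.12 for cholesterol synthesis and 0.38 for midbrain and hindbrain. The simulations therefore do not show how often a list of correlated genes passes without a shift.

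Alternatives fixed beforehand changed the pseudocount (0.01 and 1), the filter (none, or a mean of at least 5 FPKM), the scaling (quantile or median ratio), the fit (robust, only the groups compared, 2 groups), a fold minimum of 1.5, the window around Plat and the list test, and left out each library in turn. Alternatives added after seeing the data left out WT 4 and Old 1, gave them a term or used limma's library weights, added a term for libraries with Ddx3y above 1 FPKM, removed the GC trend of each library, and used an unadjusted p in the window. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.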

Results

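Brain RNA was sequenced from 12 mice aged 6 weeks, 4 in each of 3 groups. Wild-type C57BL/6J mice (WT) were set beside 2 strains that lack a working Plat gene on the same background. Plat encodes tissue-type plasminogen activator, a secreted protease that turns plasminogen into plasmin and is also made by neurons. The sample titles call the strains Old and New, and those names are used here. The labels give the tissue as cerebral cortex, while the dissection protocol describes brains from which only the olfactory bulb and cerebellum had been taken away. Transcripts of deeper regions were present in the libraries: the dopamine receptor Drd2, abundant in striatum, stood at 12.6 ± 0.928 FPKM and tyrosine hydroxylase (Th), made by dopamine neurons of the midbrain, at 3.02 ± 0.744 FPKM (SD, n = 4 WT mice). Values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), so read depth is unknown and no counting error can be given. Between 13755 and 14198 genes per library reached 1 FPKM.

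A pair of libraries from different groups, WT 4 and Old 1, stood apart from the other 10. Their Spearman correlation with each other was 0.964 across genes, against 0.921 to 0.939 with the other 10 libraries, which correlated at 0.959 to 0.972 among themselves. Genes are not independent replicates, and these coefficients describe the libraries only. In WT 4, transcripts with a GC content under 40% lay 0.71 log2 units below the 12-library mean (median; a deviation of -0.71), and those of at least 60% lay 0.63 above it. In Old 1 the medians were -0.55 and 0.70, and in the other 10 libraries they ran from 0.042 to 0.18 and from -0.19 to -0.083. Both libraries also carried Y-linked transcripts such as Ddx3y (6.51 and 8.22 FPKM), as did Old 4 (15.4 FPKM) and New 1 (13.4 FPKM).

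**Figure D1:**
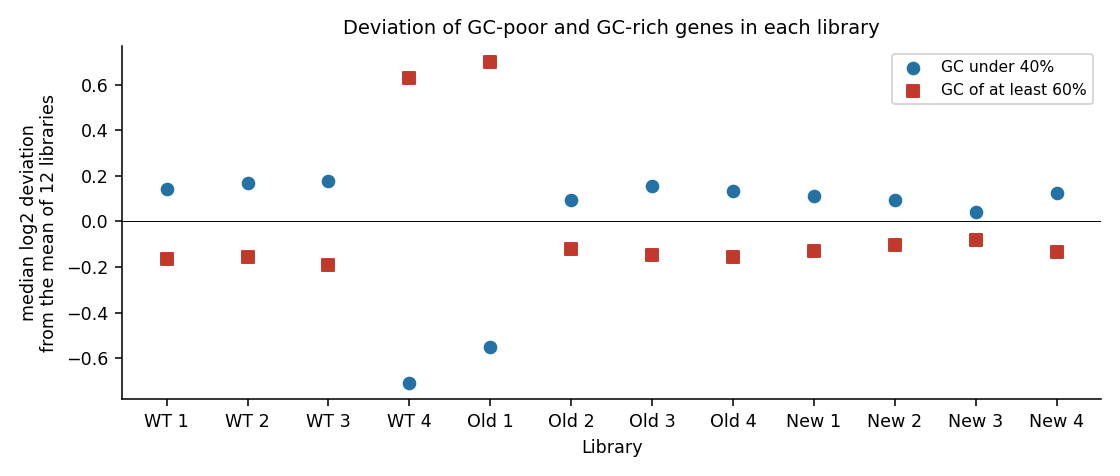
Median log2 deviation from the mean of the 12 libraries (vertical axis) of transcripts with low GC content (blue circles, under 40%) and high GC content (red squares, at least 60%), for each library (horizontal axis). WT 4 and Old 1 lie at -0.71 and -0.55 for low GC and at 0.63 and 0.70 for high GC, away from the other 10 libraries.

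Plat was examined first, as a check of the genotype labels. Plat (chromosome 8, 22757727 to 22782844, plus strand, mm10, protein-coding) was expressed at 8.43 ± 1.24 FPKM in WT brain (SD, n = 4), at 1.76 ± 0.296 FPKM in the Old strain (n = 4) and at 2.88 ± 0.182 FPKM in the New strain (n = 4). The remaining transcript was 20.9% of the WT mean in Old and 34.1% in New. All 8 knockout libraries lay below every WT library, with highest values of 2.09 FPKM in Old and 3.15 FPKM in New against a lowest WT value of 6.93 FPKM. The fall was -2.20 (SE 0.13) on the log2(FPKM + 0.1) scale in Old (limma, adjusted p = 1.79e-05) and -1.51 (SE 0.13) in New (adjusted p = 0.00212). An exact two-sided permutation test of 4 against 4 gave p = 0.0286 for each strain, the smallest value this design allows. Old also lay below New in all 4 libraries, by -0.69 (SE 0.13), but this difference did not pass the adjustment over all tested genes (limma, adjusted p = 0.807). It passed with library weights (adjusted p = 0.0487; range 0.0487 to 1 over the alternatives). A gene-level FPKM pools all exons, and the labels do not say which part of Plat either mutation removed.

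**Figure D2:**
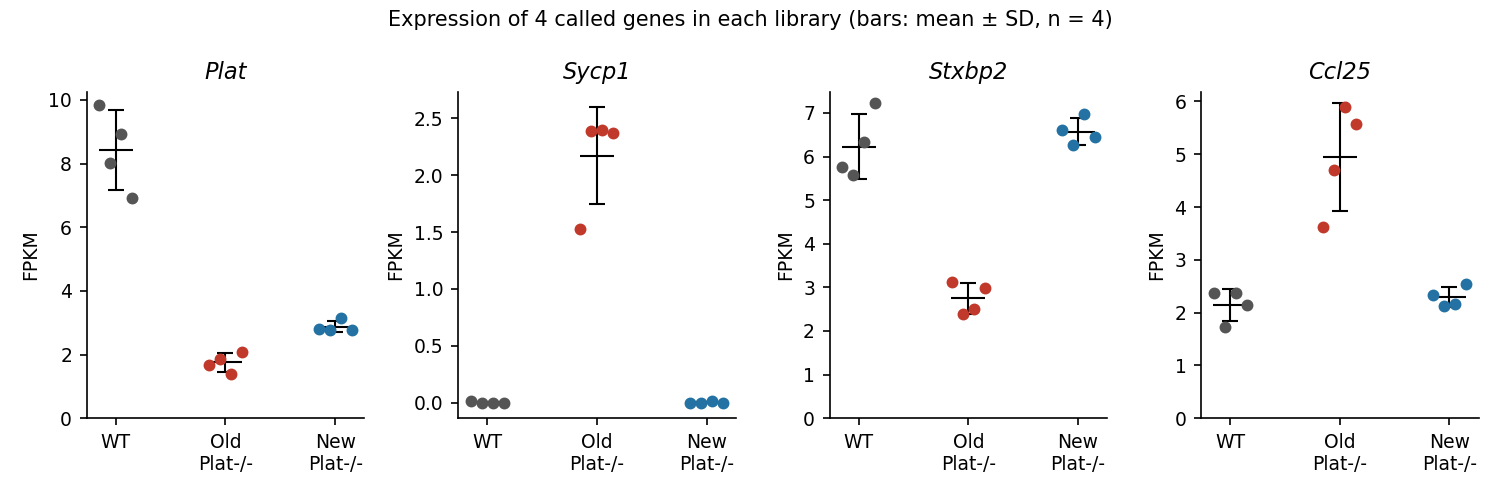
FPKM (vertical axes, linear) of Plat, Sycp1, Stxbp2 and Ccl25 in each library of the WT, Old and New groups. Points are single libraries and bars give the mean ± SD (n = 4). Plat is lower in both knockout strains, at 1.76 and 2.88 FPKM against 8.43 FPKM in WT, while the other 3 genes differ from WT in Old alone among the called comparisons.

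The first comparison asked how the Old strain differed from WT brain. Besides Plat, 3 genes differed. Sycp1, which encodes a protein of the synaptonemal complex that pairs chromosomes in meiosis, was present at 2.17 ± 0.428 FPKM in Old (SD, n = 4) and was listed at 0 in 3 of the WT libraries and at 0.0161 FPKM in WT 1. Stxbp2, which encodes Munc18-2, a regulator of granule and vesicle release, fell from 6.22 ± 0.749 to 2.75 ± 0.359 FPKM (SD, n = 4 each), a 2.22-fold reduction. Ccl25, a chemokine best known from thymus and small intestine, rose from 2.15 ± 0.305 to 4.95 ± 1.02 FPKM (SD, n = 4 each), a 2.22-fold increase. For each of the 3 genes all 4 Old libraries lay outside the WT range.

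Sycp1 (chromosome 3, 102818499 to 102936100, minus strand) rose by 4.43 (SE 0.27; limma, adjusted p = 1.79e-05) on the log2(FPKM + 0.1) scale. Since it stood at or near 0 in WT, that size depends on the pseudocount and ran from 1.65 to 7.40 over the alternatives. Stxbp2 (chromosome 8, 3630955 to 3643644, plus strand) changed by -1.15 (SE 0.11; adjusted p = 0.00134) and Ccl25 (chromosome 8, 4325210 to 4360020, plus strand) by 1.15 (SE 0.15; adjusted p = 0.0364). Each of the 3 gave an exact permutation p of 0.0286, the smallest possible. In total 4 of 16203 tested genes passed, 2 higher and 2 lower, and 270 had an unadjusted p under 0.05, where 810 would be given by chance alone. Without WT 4 and Old 1 the count was 8, and 982 genes had an unadjusted p under 0.05. The Ccl25 call was lost in 11 of 21 alternatives, including the removal of any WT library or of Old 2, Old 3 or Old 4 (adjusted p 0.00114 to 0.537 over all 21), and the Stxbp2 call was lost when Old and WT were fitted without New (adjusted p = 0.0828; range 2.66e-05 to 0.0828). The library kit does not mark strand, and the start of Ccl25 overlaps the start of Elavl1 on the opposite strand, which stood at 15.1 ± 3.47 FPKM in WT and 15.97 ± 3.08 FPKM in Old (SD, n = 4 each).

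Among gene groups, cholesterol synthesis genes ranked higher in Old than in WT. All 24 measured members had a positive difference, with a median of 0.12 on the log2 scale, and none passed singly. The median of all tested genes was 0.03, and without WT 4 and Old 1 the cholesterol median was 0.07, with 20 of 24 members above WT. Sqle, a rate-limiting oxidase of the pathway, stood at 16.8 ± 1.94 FPKM in WT and 18.9 ± 0.989 in Old, and Acat2 at 4.92 ± 0.596 and 5.27 ± 0.260 FPKM (SD, n = 4 each). Markers of midbrain and hindbrain neurons ranked lower, with 9 of 11 members below WT. The dopamine transporter Slc6a3 stood at 2.04 ± 0.764 FPKM in WT and 1.02 ± 0.850 in Old, and the serotonin-synthesis gene Tph2 at 1.24 ± 1.11 and 0.449 ± 0.396 FPKM, with wide spread between mice of 1 group. Heat shock genes ranked lower in 13 of 18 members, among them Ahsa1, an activator of Hsp90 (45.5 ± 1.98 and 42.7 ± 0.783 FPKM), although Dnajb1 stood higher (11.9 ± 0.723 and 13.4 ± 2.02 FPKM). Striatal genes ranked lower in 16 of 21 members, Drd2 among them (12.6 ± 0.928 and 11.0 ± 0.302 FPKM).

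With limma's camera at a preset correlation of 0.01, these 4 of 35 lists passed (adjusted p = 9.18e-05 for cholesterol synthesis, 7.67e-05 for midbrain and hindbrain, 0.0341 for heat shock and 0.0202 for striatum). With an estimated correlation none passed (adjusted p = 0.289, 0.329, 0.329 and 0.289 in the same order). The striatal call was lost without WT 2, WT 4, Old 1 or Old 4 (adjusted p 0.0821 to 0.768) and without WT 4 and Old 1 together (0.782), and the heat shock call without any 1 of the WT libraries, Old 2 or Old 4 (0.0506 to 0.205). A term for libraries with Ddx3y also ended the heat shock call (0.0750). The heat shock call was stronger without WT 4 and Old 1 together (adjusted p = 4.86e-05), with 17 of 18 members lower, as many as under median ratio scaling or quantile normalization. None of the members of these 4 lists passed when adjusted over the list alone. Oligodendrocyte and myelin genes (19 of 27 higher, adjusted p = 0.0819) and thalamic genes (14 of 18 higher, 0.0521) did not pass, but did under quantile normalization (0.0378 and 0.0382) and median ratio scaling (0.0436 each). Glucocorticoid response genes as higher (0.116) and mural cell genes as lower (0.0534) likewise passed only under these scalings and some other alternatives (0.0378 and 0.0436 for each list). Oxidative phosphorylation genes (0.0732) passed as higher without WT 4, Old 2, Old 3 or Old 4 (0.000794 to 0.0123). The myelin list also passed with the GC trend removed (0.0109) or a term for WT 4 and Old 1 (0.0381). The other 31 lists, those just named included, did not pass. Adjusted over the list alone, 1 reactive astrocyte gene was lower and 2 genes of the cerebellum and olfactory bulb list were higher, against 0 over all genes tested. Among these lists the immediate early genes (adjusted p = 0.861) passed as higher in Old without WT 4 or Old 3 (0.00577 and 0.0123) and as lower without Old 1 (0.0224); Fos, a member, ran from 5.37 to 23.7 FPKM within WT and from 7.08 to 25.75 FPKM within Old. In the list of Plat and the fibrinolysis system, Plat was the 1 member of 16 that passed, over all genes tested and adjusted over the list alone. Of the 16 members 9 lay above WT and 7 below, and closeness to WT was not tested. Among its partners and inhibitors, neuroserpin (Serpini1) stood at 52.5 ± 15.8 FPKM in WT and 53.9 ± 12.5 in Old. Protease nexin-1 (Serpine2) stood at 46.5 ± 5.70 and 48.1 ± 2.84 FPKM, and the receptor Lrp1 at 47.2 ± 8.58 and 47.2 ± 8.73 FPKM. The related urokinase gene Plau stood at 0.793 ± 0.119 and 0.759 ± 0.0887 FPKM (SD, n = 4 each). The Serpini1 difference turned from 0.065 to -0.196 (log2) without WT 4. A list of receptors and substrates linked to the protease in brain had 0 of 25 members past the threshold.

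The second comparison asked how the New strain differed from WT. Plat was the 1 gene of 16203 that passed. Sycp1 was listed at 0 in 3 New libraries and at 0.0157 FPKM in New 3. Stxbp2 stood at 6.57 ± 0.309 FPKM and Ccl25 at 2.29 ± 0.189 FPKM (SD, n = 4), with differences from WT of 0.08 (95% interval -0.15 to 0.32) and 0.10 (-0.24 to 0.43) on the log2 scale. Unadjusted p under 0.05 was reached by 360 genes, where chance gives 810. Without WT 4 and Old 1 the gelsolin gene Gsn also passed (2 genes in all; Gsn adjusted p = 0.00328), and 1744 genes had an unadjusted p under 0.05.

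Cholesterol synthesis genes ranked higher in New as well, in 23 of 24 members. Acat2 stood at 4.92 ± 0.596 FPKM in WT and 6.36 ± 0.562 in New, and Sqle at 16.8 ± 1.94 and 19.3 ± 1.37 FPKM (SD, n = 4 each). Oligodendrocyte and myelin genes ranked higher in 21 of 27 members (median 0.12, against 0.06 for all tested genes; 15 of 27 and a median of 0.06 under median ratio scaling), with Mog at 24.6 ± 4.58 and 32.3 ± 1.54 FPKM and Cldn11, a tight junction protein of myelin, at 53.8 ± 6.93 and 66.5 ± 3.36 FPKM. Cytosolic ribosomal protein genes ranked lower in 35 of 55 members (47 of 55 under median ratio scaling and 45 of 55 with the GC trend removed), with Rpl35 at 258.8 ± 75.4 and 202.4 ± 12.0 FPKM and Rps26 at 164.6 ± 47.5 and 133.5 ± 8.35 FPKM. WT 4 stood at 371.0 FPKM for Rpl35, and the other 3 WT libraries at 213.0 to 235.3 FPKM.

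These 3 lists passed camera at the preset correlation (adjusted p = 2.64e-05, 0.0437 and 0.00221), and none passed with an estimated correlation (adjusted p = 0.719, 0.878 and 0.878). None of their members passed when adjusted over the list alone. The other 32 lists did not pass. Adjusted over the list alone, 1 gene each of the glucocorticoid, microglia and inflammation lists was higher, against 0 over all genes tested. Midbrain and hindbrain genes (8 of 11 lower, camera adjusted p = 0.194) passed as lower with no filter (0.000434) and with library weights (0.0328). They also passed without WT 4 or New 4 (0.00282 and 0.0111). Heat shock genes (8 of 18 lower, 0.439) passed as lower without WT 4 and Old 1 (0.0294) and with library weights (0.0406). The immediate early genes (adjusted p = 0.733) passed as higher in New without WT 4 or New 3 (0.000193 and 0.00257) and without WT 4 and Old 1 (0.00031). They also passed as higher with a term for WT 4 and Old 1 (0.000114) or library weights (4.13e-09). Fos ran from 5.69 to 24.2 FPKM within New. The ribosomal call was lost without WT 4 (adjusted p = 0.850; 0.682 without WT 4 and Old 1, when 30 of 55 members lay above WT) and under quantile normalization (0.0860). The myelin call was lost without any 1 of WT 1, WT 2, WT 3, New 1, New 2 or New 4 (adjusted p 0.0670 to 0.185), and was stronger without WT 4 (0.00111), New 3 (0.00199) or WT 4 and Old 1 together (0.00031). A term for libraries with Ddx3y also ended the myelin call (0.0939). In the fibrinolysis list Plat was again the 1 member of 16 that passed, over all genes and adjusted over the list alone, with Serpini1 at 59.6 ± 2.27 FPKM and Plau at 0.791 ± 0.150 FPKM in New (SD, n = 4).

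Differences common to both knockout strains can go with the loss of Plat or with the origin of the animals. Both strains share each of these against WT, so the design cannot part them. Plat was the 1 gene called in both strains. Independent lists would give 0.000123 such genes, and 100 simulations of unchanged groups set against the same WT libraries gave a mean of 0.01. Since Plat is disrupted in both strains, its call was set by the design, and these figures do not bear on a shared response. Across genes, the changes in Old and New against WT correlated at 0.43, below the 0.50 that shared WT libraries gave in the simulations with no effect, and their covariance was 0.0591 against a simulated 0.0798. When the WT libraries were divided so that each strain had its own 2, the correlation over 6 divisions averaged -0.13 (-0.21 to -0.02). The simulations drew each library independently and left out the deviation shared by WT 4 and Old 1. That deviation is also in the divided groups, so neither value decides whether the strains share a response. With the mean of both strains set against WT, limma called Plat (-1.85, SE 0.11; adjusted p = 4.81e-05) and Sycp1 (2.21, SE 0.23; adjusted p = 0.00641), the latter carried by the Old libraries. The Sycp1 call in this mean was lost without Old 4, where 1 gene remained. Gsn became a second gene called in both strains without WT 4 and Old 1 (adjusted p = 0.0228 in Old, 0.00328 in New and 0.00318 for their mean). Camera at the preset correlation passed 4 lists: cholesterol synthesis (24 of 24 members higher, adjusted p = 1.62e-06), oligodendrocyte and myelin (19 of 27 higher, 0.0277), midbrain and hindbrain (9 of 11 lower, 0.00219) and striatum (12 of 21 lower, or 17 of 21 under median ratio scaling or quantile normalization, 0.0118). None passed with an estimated correlation (lowest adjusted p = 0.424). The striatal call was lost without WT 2, WT 4 or Old 1 (adjusted p 0.114 to 0.717), the midbrain call without WT 1 or WT 3 (0.0608 and 0.118), and the myelin call without any 1 of 7 libraries, WT 1, WT 2, WT 3, Old 1, Old 4, New 2 or New 4 (0.0610 to 0.318). With a term for libraries with Ddx3y the myelin call was lost as well (0.204). Heat shock genes did not pass, but did as lower without WT 4 and Old 1 (camera adjusted p = 0.000542). They also passed with a term for these libraries (0.00429), library weights (0.00151) or the GC trend removed (0.00673). Immediate early genes passed as higher only in alternatives, among them those without WT 4 (0.000553) or without WT 4 and Old 1 (0.0262). Others were the term for these libraries (0.0228) and library weights (0.000266).

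The third comparison set the strains directly against each other. Sycp1 was higher in Old by 4.43 (SE 0.27; limma, adjusted p = 3.53e-05) and Stxbp2 was lower by -1.23 (SE 0.11; adjusted p = 9.59e-04), a 2.35-fold difference between 2.75 ± 0.359 FPKM in Old and 6.57 ± 0.309 FPKM in New (SD, n = 4 each). These 2 of 16203 genes passed, and 184 had an unadjusted p under 0.05 where chance gives 810. Ccl25 was higher in all 4 Old libraries than in any New library, but its adjusted p was 0.0845 (difference 1.06, SE 0.15). Leaving out Old 1 alone gave Ccl25 an adjusted p of 0.012. Without WT 4 and Old 1 the count was 6, and it was 14 with library weights.

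Ribosomal protein genes ranked higher in Old than in New in 44 of 55 members, and oxidative phosphorylation genes in 46 of 61. Rps26 stood at 163.4 ± 42.7 and 133.5 ± 8.35 FPKM and the cytochrome oxidase subunit gene Cox6c at 320.8 ± 69.99 and 266.5 ± 20.9 FPKM (SD, n = 4 each), with Old 1 alone at 226.8 FPKM for Rps26. Genes of motile cilia in ependymal cells ranked higher in 6 of 10 members, led by Ccdc153 (2.29 ± 0.303 and 1.56 ± 0.0539 FPKM), the 1 member that passed when adjusted over the list alone. The 3 lists passed camera at the preset correlation (adjusted p = 6.29e-04, 0.00218 and 0.0345) and not with an estimated correlation (adjusted p = 0.78 for each). The other 32 lists did not pass; adjusted over the list alone, Plat was lower in the fibrinolysis list and 1 gene of the unfolded protein response list was higher, against 0 over all genes tested. Among these lists the immediate early genes (adjusted p = 0.943) passed as lower in Old without Old 1 or New 3 (3.21e-05 and 0.00784) and without WT 4 and Old 1 (0.0003). They also passed as lower with a term for WT 4 and Old 1 (1.52e-05), library weights (1.05e-09) or a sex term (0.00392). Oligodendrocyte and myelin genes (adjusted p = 0.384) passed as lower in Old without Old 1 (0.0249), without WT 4 and Old 1 (0.00612) and with library weights (9.31e-05). Without Old 1 the ribosomal and oxidative phosphorylation calls were lost (adjusted p = 0.669 and 0.471); without WT 4 and Old 1 their direction turned, with 32 of 55 and 36 of 61 members lower in Old (0.403 and 0.333). The ependymal call was lost without Old 4, New 2 or New 3 (adjusted p 0.0516 to 0.252), and quantile normalization ended all 3 (0.0557 to 0.137).

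The fourth comparison concerned the chromosome around Plat, since a strain can keep a segment of the chromosome on which its mutation was made. Stxbp2 and Ccl25 both lie on chromosome 8 within 20 Mb of Plat, and Sycp1 lies on chromosome 3. Further genes near Plat, named after their values were seen, stood higher in Old: the pseudogene 6820431F20Rik (10.7 ± 3.52 FPKM against 5.37 ± 1.40 in WT and 5.88 ± 0.873 in New), the long noncoding RNA ENSMUSG00000097230.1 (3.20 ± 0.748 against 1.70 ± 0.478 and 1.72 ± 0.202) and Fcer2a (1.23 ± 0.307 against 0.676 ± 0.165 and 0.600 ± 0.209; SD, n = 4 each). Pex11c, a peroxisome gene, stood lower (0.421 ± 0.0705 against 0.765 ± 0.155 and 0.703 ± 0.100 FPKM). None of these 4 passed the adjusted threshold in the fit chosen beforehand. Without WT 4 and Old 1, 6820431F20Rik and ENSMUSG00000097230.1 passed in Old against New (adjusted p = 0.0231 and 0.004) and in Old against WT (0.0429 and 0.0228). With the GC trend removed ENSMUSG00000097230.1 passed in both comparisons (adjusted p = 0.000162 and 0.000324), and with library weights Fcer2a passed in Old against New (0.0307). 6820431F20Rik overlaps a noncoding gene on the opposite strand, so its reads may belong to either.

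Within 10 Mb of Plat, the window set before the data were examined, 0 of 107 tested genes passed limma's adjusted threshold in any comparison, while 10, 1 and 11 had an unadjusted p under 0.05 in Old against WT, New against WT and Old against New. Within 20 Mb, 2 of 200 genes passed in Old against WT and 1 of 15666 elsewhere (Fisher's exact test, p = 4.70e-04, adjusted p = 0.00151 over 32 such tests). In Old against New 1 of 200 and 1 of 15666 elsewhere passed, which did not hold after adjustment (Fisher's exact test, p = 0.0251, adjusted p = 0.0534). At an unadjusted p under 0.05, a criterion added after seeing the data, 23 of 200 window genes (11.5%) and 1.52% of genes elsewhere shifted in Old against WT (Fisher's exact test, p = 2.33e-13, adjusted p = 3.73e-12). In Old against New 21 of 200 (10.5%) and 1.01% elsewhere shifted (Fisher's exact test, p = 9.34e-15, adjusted p = 2.99e-13), 12 higher and 9 lower in Old. In New against WT 3 of 200 (1.5%) and 2.2% elsewhere shifted (Fisher's exact test, p = 0.805). Between Old and New, 8 of 30 genes shifted in the interval from 20 to 25 Mb, which holds Plat, and 3 of 10 from 15 to 20 Mb. The counts were 2 of 46 from 10 to 15 Mb, 0 of 5 from 5 to 10 Mb and 8 of 32 from 0 to 5 Mb. On the other side of Plat, 0 of 33 shifted from 25 to 30 Mb. Neighbouring genes are not independent, so these p-values describe clustering of positions and not separate effects.

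**Figure D3:**
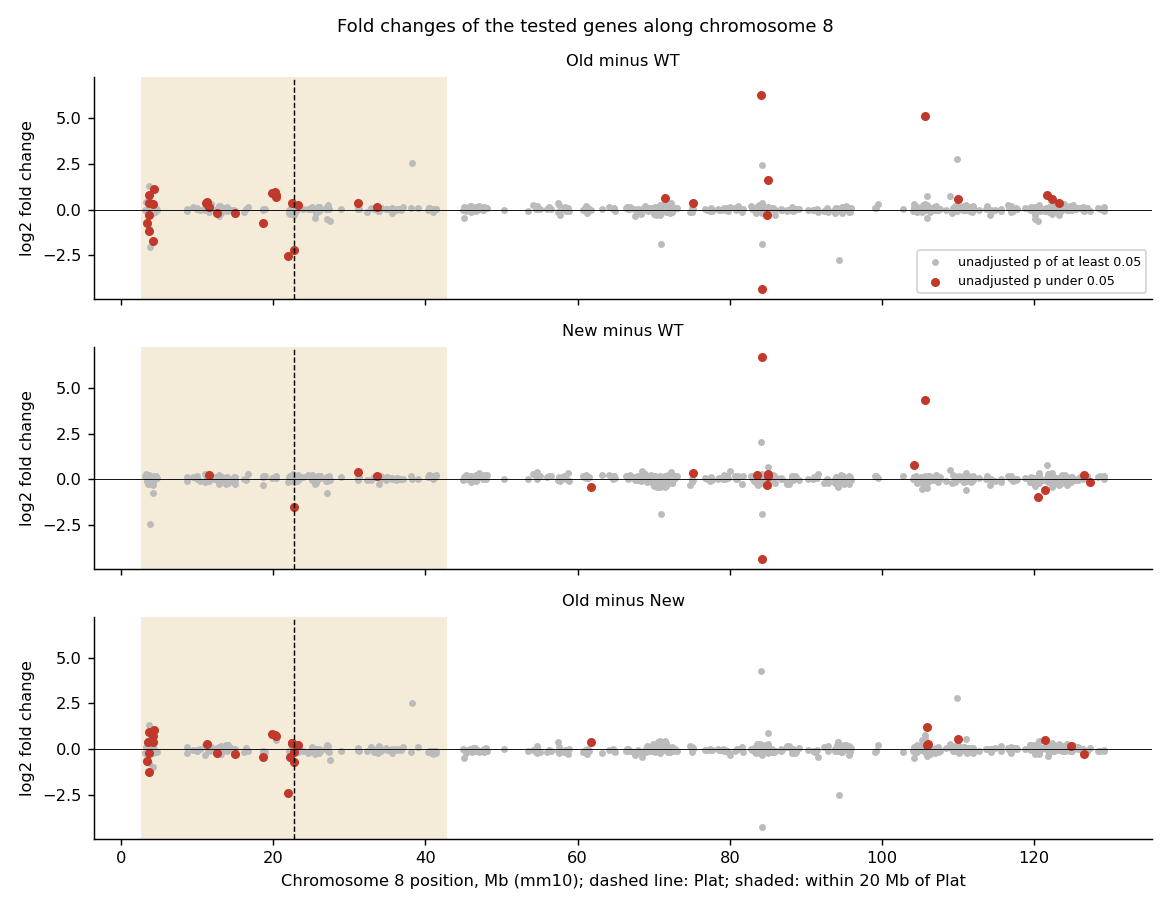
Log2 fold change (vertical axes) of each tested gene on chromosome 8 by position in Mb (horizontal axis) for Old minus WT, New minus WT and Old minus New. Red points have an unadjusted p under 0.05, the dashed line marks Plat and shading the 20 Mb on each side; in that window 23, 3 and 21 of 200 genes other than Plat are red.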

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

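The tests of how many genes other splits of the libraries call, and that of GC content, were chosen before their results were seen, except the count of window genes in splits of Old against WT and the ratio of shares in the window and elsewhere; these and the other tests in this part, on a chromosome 8 segment, reads lost at sequence differences, the divergent libraries in the window, germ cell RNA, the surroundings of Sycp1, male sex and ribosomal RNA precursor, were chosen after.

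For Old against WT, 1 of the 35 splits of the 8 libraries, the real one, called as many as 4 genes (highest other 2). That is the smallest share 35 splits allow, and the 4 genes include Plat, whose loss defines the groups. Splits with WT 4 and Old 1 on the same side are also unlike the real split, which parts them. Chance is therefore not excluded for the genes beyond Plat. For New against WT, 6 of 35 splits called at least 1 gene (highest other 2). The 1 gene of the real split was Plat, whose loss defines the groups, so this count does not bear on other genes. For Old against New 2 of 35 called at least 2 (highest other 2), so chance is not excluded for that count either. For both strains against WT, 4 of 100 drawn splits called at least 2 genes, the real one included, and the highest other split called 3; 100 draws do not part that share from 5%, so chance is not excluded. The split of WT 1, WT 2, WT 3 and Old 3 against WT 4, Old 1, Old 2 and Old 4 put 4832 genes at an unadjusted p under 0.05. It called 0 after adjustment, while the real split had 270 such genes and called 4. Splits of Old against WT with WT 4 and Old 1 on the same side put 2564 to 4832 genes there. Splits that parted this pair put 141 to 343, so this structure other than genotype goes with the divergent pair.

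The genes near Plat form the first pattern. Of genes within 20 Mb, 10.5% shifted between Old and New and 1.01% elsewhere, and the real split of the 8 libraries, with 21 shifted window genes, was the 1 of 35 that reached that number (highest other 14), while for Old against WT 16 of 35 splits reached the real 23 (highest other 59). Other splits can shift many genes across the whole genome, so the ratio of the share in the window to that elsewhere was also taken. In Old against New 1 of 35 splits, the real one, reached 10.3 (highest other 4.08). In Old against WT 1 of 35, again the real one, reached 7.45 (highest other 2.51). A share of 1 in 35 is the smallest these splits allow. The ratio and its unadjusted p were also chosen after seeing the data, so chance is not excluded for the excess. Leaving out WT 4 and Old 1 left 19% of window genes shifted against 4.64% elsewhere, which argues against these libraries as the cause. Of the 21 genes 12 were higher in Old (95% lower limit 34.0%, which treats neighbouring genes as independent). Reads lost at sequence differences from the reference would lower a gene, which argues against such loss alone for the 12. Reads divided differently between near-identical or overlapping genes were not tested as a cause of the higher values. For the 9 lower genes such loss and a true fall cannot be told apart. Chance and a chromosome 8 segment that only the Old strain carries stay open. Such a segment would give an excess near Plat over genes elsewhere in both Old comparisons and not in New against WT. Effects of the Plat mutation in Old on its neighbours stay open as well, and no variant was examined.

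Sycp1 in Old is the second pattern; it was marked because the effects in the strains differed by 4.43 (log2, limma adjusted p = 3.53e-05). Germ cell RNA in the Old libraries would bring other germ cell transcripts. But 40 other genes of a list written for this test had a median difference between Old and New of -0.0237 (bootstrap limits -0.109 to 0.0546, 10000 draws). The draws resampled genes and not mice, so these limits do not measure the spread between animals. The test was first run on the 9 of these genes that passed the expression filter (median -0.0812) and then widened to all 40, of which 29 lay below 0.5 FPKM in Old; the highest single difference was 1.31. A run of shifted genes around Sycp1 like that on chromosome 8 is argued against by 0.465% of 215 genes within 10 Mb shifted (95% upper limit 2.56%). This limit treats neighbouring genes as independent. A change at the Sycp1 locus itself in the Old strain and transcripts joined to it stay open and were not tested.

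The divergence of WT 4 and Old 1 is the third pattern: their median Spearman correlations with the other libraries were 0.929 and 0.934, each far from the other 3 of its group. Removing the GC trend raised the values over genes with a known GC content from 0.930 and 0.935 to 0.954 and 0.956. Both stayed below the lowest of the other 10, at 0.963, by more than the range of those 10 (0.0062). That was the limit set beforehand for arguing against GC content bias, so the values argue against the removed trend as the whole cause. The pair still correlated at 0.966 with each other. Given the rise, GC content bias may account for part of the gap. The trend rested on 1 GC value per gene, that of its longest transcript, and may leave bias behind. Whether bias that the trend missed accounts for the rest cannot be told. Male sex is argued against as the cause by Old 4 and New 1, which carry Y-linked transcripts and correlated at 0.966 or more. Ribosomal RNA precursor carry-over stays open: Rn45s stood at 53018 FPKM in WT 4, 31230 in Old 1 and 32394 in WT 2, which correlated at 0.966, and at 16412 or less in the other 9, but 1 library decides nothing. Library batch, RNA quality and dissection stay open, since no lane or batch is given per sample, and no biological explanation other than sex was tested; genotype does not set the pair apart, because it crosses the groups.

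Stxbp2 was marked because its effects in the strains differed by -1.23 (log2, limma adjusted p = 9.59e-04). Groups were also examined for single libraries far from the other 3 of their group. Some genes came from lists whose calls rested on WT 4 or Old 1, and the correlations that set this pair apart were counted too. An excess in these libraries was therefore partly built in. Such single libraries were found in 29 of 183 groups examined, where chance gives 9.15 for independent groups with normal spread. Of the 29, 18 lay in WT 4 or Old 1. In WT 4 these were Tm7sf2 at 4.75 FPKM, Hsd17b7 at 3.31, Serpine2 at 37.9, Vtn at 21.5, Lrp1 at 59.99, Rpl35 at 371.0, Rps12 at 300.4, Rps26 at 235.9 and Cox6c at 413.5 FPKM. In Old 1 they were Sycp1 at 1.53 FPKM, Dnajb1 at 16.4, Lrp1 at 60.15, Rpl35 at 332.5, Rps12 at 287.0, Rps26 at 226.8 and Cox5b at 217.9 FPKM. In the remaining libraries they were Sycp1 at 0.0161 FPKM in WT 1, Fdps at 17.2 in WT 3, Thbd at 4.67 in Old 3 and Tph2 at 1.04 FPKM in Old 4. In New they were Cox5b at 147.7 FPKM in New 1, Plat at 3.15, Sycp1 at 0.0157, Ndufb4 at 110.3 and Lrp1 at 45.3 FPKM in New 3, and Th at 3.20 and Tph2 at 1.24 FPKM in New 4.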

How the results depend on the processing

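The alternatives that leave out or weight WT 4 and Old 1, add a sex term, remove the GC trend or use an unadjusted p in the window were chosen after seeing the data. The fall of Plat passed in both strains in all 21 alternatives that tested it, from -2.30 to -1.77 in Old and from -1.62 to -1.27 in New; a mean of at least 5 FPKM removed Plat, Sycp1 and Ccl25. Across the other genes named by rule and the alternatives, in the 3 comparisons of 2 groups, 3312 values kept direction and side of the threshold, 12 lost their call and 4 gained one (Ccl25 in Old against New). Another 233 changed direction, in 71 pairs of gene and comparison, with 0 called before or after (lowest adjusted p 0.666). Scaling left the median of all genes within 0.1 of 0. FPKM gives no depth, so the limit set by counting is unknown. Camera was not rerun for the fold minimum, robust, 2-group and single-pair fits. Except where given, the causes were not tested.

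Genes called were 4 in Old against WT, 1 in New against WT, 2 in Old against New and 2 for both strains against WT. With a mean of at least 5 FPKM they were 1, 0, 1 and 0, with 0 called in both strains, from the loss of Plat, Sycp1 and Ccl25. Only the groups compared gave 2 in Old against WT. For both strains against WT, a pseudocount of 0.01, quantile normalization and a 2-group fit each gave 1, as Sycp1 lost its call. Stxbp2 gained one there with a term for WT 4 and Old 1 (adjusted p = 0.0240), weights (0.0197), a sex term (0.0464) and GC removal (0.0484). Without WT 4 and Old 1 the counts were 8, 2 and 6, with 2 called in both strains. With a term for them they were 8, 2, 7 and 5, with 2 called in both strains, and with limma's library weights 8, 2, 14 and 5. Removing the GC trend gave 4 in Old against New. Plat in Old against New, at -0.69, passed with weights (-0.68, adjusted p = 0.0487; 0.0487 to 1 over its alternatives).

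Within 10 Mb of Plat 0 genes were called. Leaving out WT 4 and Old 1, or a term for them, gave 3 in Old against WT and 3 in Old against New; weights gave 3 and 6, and GC removal 2 and 2. Windows of 20 Mb or all of chromosome 8 gave 2 and 1, because they reach Stxbp2 and Ccl25. An unadjusted p gave 10 in Old against WT, 1 in New against WT and 11 in Old against New.

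Lists passing camera were 4, 3, 3 and 4 in the same order of comparisons. Both an estimated correlation and fry's directional test gave 0 in each. No filter gave 2 in Old against WT and 5 in New against WT. Quantile normalization gave 8 in Old against WT and 0 in Old against New, and median ratio scaling 8 in Old against WT. Without WT 4 and Old 1, New against WT had 6 and both strains 7; with a term both strains had 7, with weights New against WT had 7, and with a sex term Old against New had 6. At the preset correlation the cholesterol list passed in each of 19 alternatives for Old and for New against WT (highest adjusted p 0.0322 and 0.00236), and with an estimated correlation it did not (adjusted p = 0.289 and 0.719). Lists that did not pass in the fit chosen beforehand, but did in at least 1 alternative, numbered 11, 13, 8 and 11.

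With 1 library left out, genes called ran from 3 to 4, 1 to 1, 2 to 3 and 1 to 3 (1 without Old 4), called in both 1 to 1, and near Plat 0 to 0. Plat ran from -2.29 to -2.10, -1.60 to -1.43 and -0.77 to -0.59. Lists ran from 3 to 9 (9 without Old 3), 2 to 7 (7 without WT 4, 5 without New 3), 2 to 6 (6 without Old 3 or New 3) and 3 to 10 (10 without WT 4).

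Among the uncalled differences that changed direction were the following (log2). Quantile normalization in Old against WT: Rpl12 -0.0073 and Anxa2 -0.028. Quantile normalization in New against WT: Rps18 -0.025, 5033414D02Rik -0.0045, Anxa2 -0.039 and Thbd -0.047. Quantile normalization in Old against New: Cryab -0.0084, Hsd17b7 0.0077 and Anxa2 0.011. Median ratio scaling in Old against WT: Rpl12 -0.014 and Anxa2 -0.020. Median ratio scaling in New against WT: Rps18 -0.052, 5033414D02Rik -0.0022, Anxa2 -0.035 and Thbd -0.047. Median ratio scaling in Old against New: Hsd17b7 0.0088, Cnp 0.0027, Rpl9 0.0026, Anxa2 0.015 and F3 0.014. Old against WT without WT 4 and Old 1: Serpine2 -0.0013, Serpini1 -0.0075, Rps26 0.013 and Rpl12 -0.022. New against WT without WT 4 and Old 1: Rgs9 0.021, Serpini1 -0.017, Rpl30 -0.60, Lrp1 0.0021, F3 -0.022, Thbd -0.015, Vtn 0.045 and Pros1 -0.0090. Old against New without WT 4 and Old 1: Cryab -0.052, Hsd17b7 0.0089, Serpini1 0.0094, S100a10 -0.032, Lrp1 -0.0043, F3 0.061, Vtn -0.082 and Pros1 0.040. A term for these libraries in New against WT: Hspa1b 0.030, Rpl30 -0.25, Cox5b 0.0025, Lrp1 0.0029, Thbd -0.034 and Vtn 0.059. A term for these libraries in Old against New: Tfpi 0.039, Cryab -0.038, Tph2 0.14, Hsd17b7 0.045, Serpini1 0.046, Cldn11 0.00077, Plau 0.0046, S100a10 -0.0020, Lrp1 -0.0036, F3 0.097, Vtn -0.069 and Pros1 0.071. Library weights in Old against WT: Rgs9 0.00035, Serpine2 -0.0040, Serpini1 -0.011, Rps26 0.0071 and Rpl12 -0.027. Library weights in New against WT: Rgs9 0.011, Rpl30 -0.69, Anxa2 -0.040, F3 -0.064, Thbd -0.069, Vtn 0.022 and Pros1 -0.026. Library weights in Old against New: Tfpi 0.033, Cryab -0.016, Plau 0.017, Anxa2 0.070, S100a10 -0.017, F3 0.10, Thbd 0.053, Vtn -0.065 and Pros1 0.041. A sex term in Old against WT: Rpl12 -0.020 and Plau 0.00092. A sex term in Old against New: Tfpi 0.0087, Cryab -0.0034, Plau 0.0079, Anxa2 0.016, S100a10 -0.00060, F3 0.066 and Vtn -0.035. GC trend removal in Old against WT: Rpl12 -0.016 and Anxa2 -0.026. GC trend removal in New against WT: Ccl25 -0.043, Rps18 -0.039, 5033414D02Rik -0.061, Anxa2 -0.018 and Thbd -0.033. GC trend removal in Old against New: Tfpi 0.051, Cryab -0.032, Drd2 -0.00059, Sqle 0.014, Hsd17b7 0.074, Rpl9 0.024, Plau 0.0041, 5033414D02Rik 0.0060, F3 0.056 and Vtn -0.041.

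With 1 library left out, some that changed direction ran as follows. Serpine2 -0.039 to 0.093, Serpini1 -0.20 to 0.25, Rpl35 -0.25 to 0.097, Rps12 -0.25 to 0.076, Rps26 -0.17 to 0.18 and Rsph1 -0.15 to 0.019 in Old against WT. Rarres2 -0.0069 to 0.14, Rpl12 -0.089 to 0.084, Ndufb10 -0.064 to 0.047, Cox5b -0.014 to 0.18, Cox6c -0.15 to 0.12 and Ndufb4 -0.17 to 0.042 in Old against WT. Plau -0.12 to 0.014, 5033414D02Rik -0.076 to 0.019, Anxa2 -0.025 to 0.047, S100a10 -0.054 to 0.026, Lrp1 -0.12 to 0.12 and F3 -0.035 to 0.19 in Old against WT. Vtn -0.10 to 0.053 and Pros1 -0.12 to 0.24 in Old against WT. Sycp1 -0.054 to 0.053, Ccl25 -0.0014 to 0.15, Ahsa1 -0.045 to 0.00018, Rgs9 -0.084 to 0.021 and Serpina9 -0.14 to 0.022 in New against WT. Slc6a3 -0.38 to 0.17, Chat -0.11 to 0.058, Serpini1 -0.017 to 0.36, Ccdc153 -0.11 to 0.098, Ak7 -0.18 to 0.041 and Rarres2 -0.12 to 0.023 in New against WT. Rpl30 -0.60 to 1.00, Rps18 -0.018 to 0.045, Plau -0.12 to 0.057, Anxa2 -0.064 to 0.14, S100a10 -0.067 to 0.041 and Lrp1 -0.17 to 0.0021 in New against WT. F3 -0.022 to 0.20, F13a1 -0.17 to 0.096, Thbd -0.074 to 0.11, Vtn -0.064 to 0.045 and Pros1 -0.0090 to 0.30 in New against WT. A2m -0.013 to 0.11, F2r -0.059 to 0.12, Tfpi -0.17 to 0.0033, Hspa1b -0.39 to 0.039, Cryab -0.052 to 0.052 and Drd2 -0.018 to 0.10 in Old against New. Sqle -0.080 to 0.00096, Hsd17b7 -0.058 to 0.019, Fdps -0.097 to 0.012 and Serpini1 -0.27 to 0.0094 in Old against New. Cnp -0.092 to 0.019, Rpl9 -0.071 to 0.023, Plau -0.11 to 0.064, Anxa2 -0.13 to 0.074, S100a10 -0.050 to 0.057 and Lrp1 -0.0043 to 0.17 in Old against New. F3 -0.057 to 0.061, Thbd -0.21 to 0.00018, Vtn -0.082 to 0.069 and Pros1 -0.18 to 0.040 in Old against New. The range for Tph2, Old against New, was -0.67 to 0.18.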

Other observations

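The genes in this part were chosen after their values were seen, and none passed limma's adjusted threshold in the fit chosen beforehand. They stand for no group: the inflammation list had 9 of 20 members above WT in Old and 13 of 20 in New (adjusted p = 0.786 and 0.868), and the microglia list 17 of 26 in each (0.559 and 0.528). Ifitm1, an interferon-induced membrane protein, stood at 0.824 ± 0.185 FPKM in WT, 1.64 ± 0.322 in Old and 1.72 ± 0.227 in New (SD, n = 4 each; adjusted p = 0.688 in Old and 0.695 in New). Nfkbia, the inhibitor of NF-kappa-B, stood at 6.37 ± 0.433, 8.30 ± 0.774 and 9.36 ± 1.06 FPKM (limma adjusted p = 1 and 0.695), and the microglial adaptor Tyrobp at 9.10 ± 1.13, 11.3 ± 0.396 and 11.7 ± 0.145 FPKM (adjusted p = 1 and 0.965). Gsn, which encodes the actin-severing protein gelsolin, stood at 18.1 ± 4.67, 21.8 ± 4.40 and 21.2 ± 0.639 FPKM, and Rmnd1 at 1.06 ± 0.508, 3.14 ± 1.39 and 2.90 ± 0.576 FPKM. With library weights Gsn passed in New against WT (adjusted p = 0.0145) and Rmnd1 in Old against WT (0.0267). Gsn passed in Old and in New against WT without WT 4 and Old 1 (adjusted p = 0.0228 and 0.00328), and likewise with a term for these libraries (0.0304 and 0.00488). The animals' origin goes with genotype in these comparisons.

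Y-linked Ddx3y stood at 6.51 FPKM in WT 4, 8.22 in Old 1, 15.4 in Old 4 and 13.4 in New 1, and at 0.0242 FPKM or less in the other 8 libraries. Of those 8, New 3 had Xist at 0.00152 FPKM, while Xist stood at 1.77 to 5.89 FPKM in the other 7. Kdm6a, which escapes X inactivation, stood at 9.27 FPKM in New 3, against 7.62 in Old 4 and 7.13 in New 1.

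The noncoding gene ENSMUSG00000086930.1 on chromosome 17 stood at 2.57 ± 0.243 FPKM in WT, 2.70 ± 0.341 in Old and 1.41 ± 0.168 in New (SD, n = 4 each; limma adjusted p = 0.0634 for Old against New, and 0.0142 with library weights). It overlaps Frs3 on the opposite strand.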
